A study of Rattus norvegicus with 5 samples.

How the data were processed

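Lung RNA of rats was hybridised to 5 one-colour oligonucleotide arrays, 1 per group, and per the labels each array received a pool of equal RNA amounts. The groups, taken from the array titles, were exposure to EHC-93 at early (2, 4 and 6 h), intermediate (15, 18 and 21 h) and late (24, 32 and 40 h) times, saline sham (2, 15 and 24 h) and untreated control (3 rats). How many rats stand behind each instilled pool is not given in the sources used here. No group had a second array, so there is no replicate error within a group.

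The deposited values are 1 linear intensity per probe set and array for 8799 probe sets. That the authors scaled them between arrays is read from the values: the mean after trimming 2% at each end lay between 1001.38 and 1001.63 on the 5 arrays. The algorithm and software are not given in the sources used here, and detection calls were not used here. The table's 59 control probe sets were left out, except for the 5′ to 3′ ratios of beta-actin and GAPDH, leaving 8740. Genes were named through a platform annotation table: 7006 probe sets had 1 symbol, 308 had several and 1426 were not listed, and the latter 2 kinds stayed unnamed. Of the identifiers, 6994 were found in a RefSeq gene table of the rat assembly GRCr8, which changed no symbol; no coordinates were used.

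From the deposited intensity, values were scaled so that all arrays had the same median, with factors from 0.931 (sham) to 1.07 (intermediate), floored at the 40th percentile of all scaled values (172.53) and taken to log2. A fold against a value at the floor is a lower bound and is written with "at least", and the place of such a gene among the named genes is set by the floor. A gene was represented by the probe set with the highest mean log2 value over the 5 arrays. This choice uses no group labels, but the exposed arrays enter the mean. A probe set that reads higher on exposed arrays therefore gains rank, which can favour higher calls. For Nos2 the chosen probe set read 186 on the sham and 181 on the untreated array. Another read under the floor and 251 there. The exposed arrays, at 732, 682 and 559, put the chosen one first. The rule gave 4736 genes, 1567 of them with several probe sets, and 3667 were above the floor on at least 1 array. Other probe sets above the floor existed for 49 of the 132 genes the naming rule chose, and for 21 of these at least 1 differed in direction or by over 2-fold in the difference, counting values at the floor, which only bound a difference.

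Before the data were examined, the tests, the alternatives, 26 gene lists and the rule for named genes were fixed. For each exposed array, genes at least 2-fold higher or lower than both the sham and the untreated array were counted, with the same count for each control against the other 2 arrays of its trio as a yardstick. Sham was compared with untreated and each phase with the other phases by the same fold rule. These comparisons have no test. Exposure averaged over phases was tested with limma (lmFit and eBayes, 3 exposed against 2 unexposed arrays, 3667 genes, Benjamini-Hochberg adjustment, threshold 0.05), and the lists with at least 3 measured genes with limma's camera at a preset inter-gene correlation of 0.01. The p-values measure only the spread between these arrays, in which phase and sham differences are part of the residual. For each array the median log2 difference of a list from the mean of both controls was set against 10000 random lists of the same size, matched on mean log2 value in 20 bins; the percentile describes these arrays, since genes are not replicates. Of 471 listed symbols 337 were measured. The lists covered metal response, antioxidant and glutathione, aryl hydrocarbon receptor targets, cytokines and chemokines, acute phase and innate effectors, immediate early, extracellular matrix and remodelling, coagulation and vascular tone, cell cycle, heat shock and unfolded protein response, interferon response and antigen presentation, and markers of neutrophils, macrophages, alveolar type 1 and 2, club, ciliated, endothelial, lymphoid, erythroid, mast, cardiac, smooth and skeletal muscle cells and adipocytes, with reference genes.

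Named genes were the 12 highest and 8 lowest per exposed array by the smaller of the differences from both controls, the 6 highest and 6 lowest of sham against untreated, the 5 highest and 3 lowest of each phase against the others, the 10 smallest p of the limma fit, and per list up to 4 members passing in any phase or, with none passing, up to 3 with the highest mean. Socs3, Ccl5, Cxcl10 and Gpx2, named as the passing members behind small list counts, and the clock genes were chosen after their values were seen; of the sterol synthesis and amino acid lists, the members marked as seen were.

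The steps were tested on simulated data. For a simulated early array, the fold rule called 44% of genes raised 2-fold and 24% of genes lowered 2-fold, 88% and 84% at 3-fold and 100% of both at 4-fold, in 25 genes each, and 0.376% of 4517 unchanged genes. The changed genes were drawn only from genes with a control mean over 2-fold above the floor. Their rates therefore do not carry over to genes near the floor. The unchanged genes included those at the floor, which are seldom called and lower that rate. In simulated comparisons of 3 against 2 arrays, limma called 48% of 50 genes changed 2-fold and 86% changed 4-fold, and camera called the raised list and 0 of 24 others. The simulated changes were equal on the 3 exposed arrays and the noise was independent between genes. These limma and camera rates therefore leave out phase differences and inter-gene correlation and do not carry over to the real arrays. Alternatives were values as deposited, scaling to the 75th percentile, quantile normalization, a floor at the 20th or 60th percentile, the mean of all probe sets of a gene, leaving out probe sets with the suffixes _f_at, _r_at, _i_at or _s_at, either control alone as reference, thresholds of 1.5-fold and 3-fold, each array left out in turn for limma and camera, eBayes with trend and robust, no filter, and an estimated correlation. EST probe sets (rc_) alone or left out were added after the data were seen. Lists restricted to genes above the floor were also not planned beforehand. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.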

Results

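Lung RNA of rats was measured on 5 one-colour oligonucleotide arrays after intratracheal instillation of EHC-93, a preparation of urban outdoor dust. Each group had 1 array, hybridised with a pool of RNA. The early array held RNA from 2, 4 and 6 h after instillation, the intermediate array from 15, 18 and 21 h, and the late array from 24, 32 and 40 h. A sham array held RNA from 2, 15 and 24 h after saline instillation, and a control array held RNA from 3 rats that had not been instilled. The median deposited intensity lay between 262 on the intermediate array and 301 on the sham array, and 3167 to 3250 of the 4736 named genes were above the floor on an array. With 1 array per group a difference between single arrays has no replicate check and is given without an error or a p-value; only the comparison of the 3 exposed with the 2 other arrays has both. The number of arrays limits the precision. A gene is called higher or lower where it was at least 2-fold away from both control arrays, unless another reference is named.

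The arrays differed in the 5′ to 3′ signal ratio of control transcripts, which falls when RNA or its copy is incomplete. For beta-actin the ratio was 43.1% on the early, 9.07% on the intermediate, 19.6% on the late, 14.7% on the sham and 24.4% on the untreated array. For GAPDH it was 67.2%, 23.6%, 38.1%, 25.4% and 39.1% in the same order. Hence the early array had the highest and the intermediate array the lowest ratio of both transcripts.

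The early pool, which asks what differs in the lung within hours of the particles, had 93 genes higher and 11 lower than both controls. The sham pool held 2, 15 and 24 h, so the early times had no saline control of their own. Hspa1a, an inducible heat shock protein, had a scaled intensity of 11637 on the early array against 615 on the sham and 327 on the untreated array, 18.9-fold and 35.6-fold; a near-identical paralog makes its identity uncertain. Chemokines that attract monocytes and neutrophils were among the highest differences: Ccl2 was at 7097 against 888 on the sham and 812 on the untreated array, Ccl3 was 7.37-fold and 6.90-fold above them, and Cxcl2 was at least 8.21-fold above both. Fosl1, a subunit of the AP-1 transcription factor, and the cytokine Il6 were at the floor on the other 4 arrays and at least 6.74-fold and 5.82-fold higher here. Tissue factor F3, the starter of coagulation, reached 10016 against 2250 and 1269.

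By the lists fixed beforehand, 12 of 21 measured cytokines and chemokines were higher, none was lower and 9 did not pass, and the median difference from the mean of both controls was 1.13 on the log2 scale (percentile 100 among 10000 matched random lists). Il1b was among them at 4479 against 1131 and 692. Of 19 immediate early genes, 7 were higher, with a list median of 0.69 (percentile 100); Atf3 was 3.65-fold and 4.07-fold, Junb 3.33-fold and 2.84-fold, and Ier3 2.76-fold and 3.28-fold above sham and untreated. Acute phase and innate effector genes had 6 of 25 members higher and a median of 0.53 (percentile 100), with Nos2, the inducible nitric oxide synthase, 3.94-fold and 4.05-fold above the controls and the transcription factor Cebpd 2.59-fold and 5.44-fold. Among 25 genes of coagulation and vascular tone 4 were higher (median 0.28), namely F3, Nos2, the urokinase receptor Plaur and the vasoconstrictor endothelin Edn1, the last at 895 against 395 and 266.

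Antioxidant enzymes divided: 4 of 28 were higher, while the median of the list was -0.06 and its mean 0.20. The 4 were mitochondrial superoxide dismutase Sod2 (4.35-fold and 3.76-fold), heme oxygenase Hmox1 (3.28-fold and 9.16-fold), the quinone reductase Nqo1 (2.85-fold and 2.95-fold) and the thioredoxin reductase Txnrd1 (2.83-fold and 3.02-fold). Hmox1 was also 2.79-fold higher on the sham than on the untreated array. Hmox1 was the 1 higher member of 6 measured metal response genes, whose median was 0.34 on the early array and 0.38 for sham against untreated. The metallothioneins Mt1a, Mt1 and Mt2A and the ferritins Ftl1 and Fth1 of that list were not measured as named genes, so its median says nothing of them. Nqo1 was the 1 higher member of 6 measured aryl hydrocarbon receptor targets (median 0.45). In the heat shock and unfolded protein response list 2 of 18 members were higher, Hspa1a and Hsph1 (3.48-fold and 3.43-fold), with a median of 0.32. Moesin (Msn), the nucleoside kinase Uck2 and the growth factor Areg were further leading genes, at 1263, 891 and 1068 on the early array. Among 29 matrix and remodelling genes, Plaur, the metalloproteinase inhibitor Timp1 (2.07-fold and 2.87-fold) and the macrophage elastase Mmp12 were higher and the proteoglycan decorin Dcn lower, with a median of 0.15.

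The 11 lower genes on the early array were led by the collagen-binding integrin Itga1 (305 against 847 and 1093, log2 differences of -1.47 and -1.84) and the trafficking gene Trappc3 (-1.37 and -1.40). Cox8b, Trhr, the adipocyte protease Cfd, the vitamin D hydroxylase Cyp24a1 and Dcn followed, with log2 differences from sham between -1.27 and -1.04. Grin2a, at the floor here, was at least 2.41-fold below sham. The other probe sets of Trhr, Cyp24a1 and Grin2a lay under the floor on every array, so these calls rest on 1 probe set each. No member of the cell cycle list passed (19 measured, median -0.11).

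For scale, the sham array had 29 genes at least 2-fold above and 22 below both other arrays of the same trio, and the untreated array 17 and 14. Higher genes were 89.4% of the early calls, against 76.9% when arrays were scaled to their 75th percentile. Of the 93 higher genes, 31 had at least 1 other probe set above the floor. At least 1 such probe set passed for 16 of these 31 and differed in the same direction from both controls for 28. Probe sets did not always give the same size: the coding-region probe sets of the smooth muscle actin Acta2 were 1.28 and 1.56 above the controls on the log2 scale where its main probe set gave 0.02, and second probe sets of Hmox1 and Txnrd1 gave 3.91 and 2.81 against 2.45 and 1.55. The probe set that stands for Nos2 was not matched on the early and late arrays by the 2 other Nos2 probe sets above the floor on some array, both of which lay under it on the sham array. One read 173, 214 and 196 on the early, intermediate and late arrays against 251 on the untreated array, and the other 418 on the intermediate array against 226, and under the floor on the early and late arrays. Second probe sets of Il6 and Hsph1 read 193 and 220 on the early array and lay under the floor on the others, so they give no size. Other probe sets gave -0.28 and 2.77 for Cebpd and -0.54, -0.48 and 0.25 for Dcn on this array. With probe sets made from expressed sequence tags (EST) alone, a setting chosen after seeing the data, 34 genes were higher and 3 lower, against 8 and 10 for sham and 10 and 6 for untreated.

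**Figure D1:**
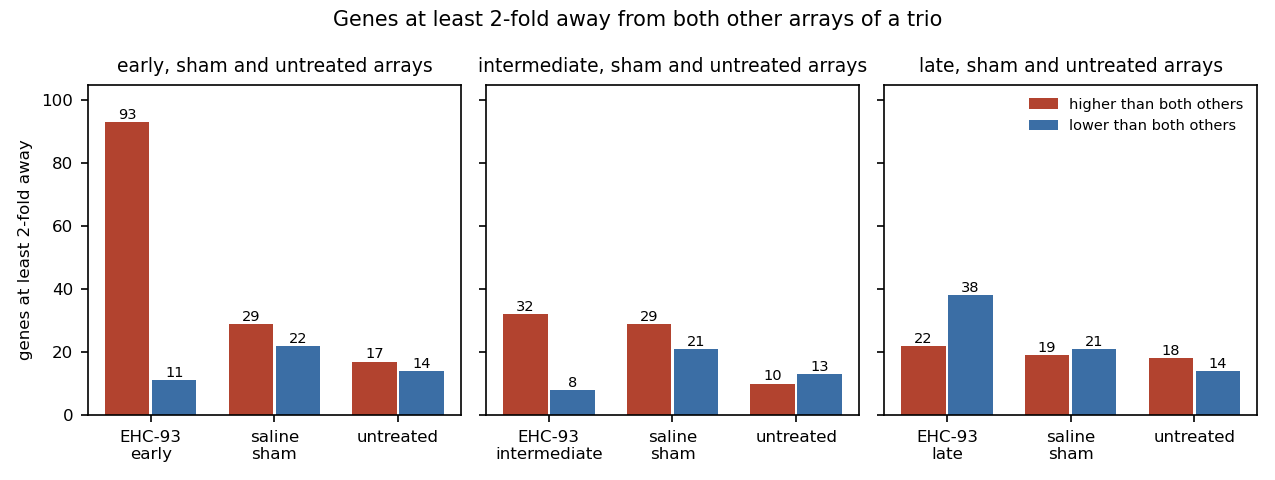
Number of genes (vertical axis) at least 2-fold higher (red) or lower (blue) on 1 array than on both others of a trio, for the trios of the early, intermediate or late array with the sham and untreated arrays. The early array had 93 higher genes, against 29 and 17 for its controls, and the late array had 38 lower genes.

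The intermediate pool, at 15 to 21 h, had 32 genes higher and 8 lower than both controls. Orm1, an acute phase plasma protein, was the leading gene at 2399 against 277 and 187, 8.65-fold and 12.9-fold. Ccl2 (6.05-fold and 6.61-fold), Ccl3 (3.57-fold and 3.34-fold), Il1b (3.05-fold and 4.99-fold) and Nos2 (3.67-fold and 3.78-fold) were higher here too. Mmp12, an elastase of macrophages, was at least 4.34-fold above sham and 3.94-fold above untreated, and Padi4, a peptidylarginine deiminase of granulocytes, was 3.47-fold and 3.12-fold above them. Complement genes were among the calls, with C3 at 13125 against 4893 and 4081 and the complement regulator C4bpa at 3111 against 1104 and 564.

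Of the fixed lists, acute phase and innate effectors had 4 of 25 members higher (Orm1, Nos2, C3 and Lcn2; median 0.32, percentile 99.8) and cytokines and chemokines 3 of 21 (Ccl2, Ccl3 and Il1b; median 0.23). Heat shock and unfolded protein response genes had the highest median, 0.74 (percentile 100), with 17 of 18 members above the controls by any amount and 2 past 2-fold, the endoplasmic reticulum chaperone Hspa5 (2.41-fold and 2.73-fold) and Hsph1. None of the 19 immediate early genes passed (median 0.02). Further calls were the activin inhibitor follistatin, Fst (3.11-fold and 3.21-fold), the replication helicase subunit Mcm6 (2.80-fold and 2.71-fold), the only one of 19 cell cycle genes to pass here (median 0.16), the glutathione-cleaving enzyme Ggt1 (at least 4.44-fold above both) and Hoga1 (at least 3.68-fold above sham). In the antioxidant list Sod2 passed (2.46-fold and 2.13-fold; median 0.18), and in the matrix list Mmp12 and Timp1 (median 0.05). In the coagulation list Nos2 alone passed (median 0.06), and medians of the metal and aryl hydrocarbon receptor lists were 0, with no member passing.

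Lower on the intermediate array were Bmyc (log2 differences of -1.39 and -1.47), the thrombin inhibitor Serpind1 (-1.38 and -1.88), the caveolar protein Cav1 (-1.35 and -1.31), Ucp1 and Hpn, with Slc8a2, Gabrr1 and Lmbr1l at the floor. A second Ccl2 probe set gave 1.53 (log2 difference from the mean of the controls). One other Bmyc probe set lay under the floor here against 455 and 451, and another read 202 against 251 on the sham array and a value under the floor on the untreated array. Cav1 had its highest value on the array with the highest 5′ to 3′ ratios and its lowest on that with the lowest. The arrays between did not follow the ratios. Cav1 read 808 on the sham array, against 535 on the late and 783 on the untreated array, which had higher ratios than sham. In this trio the sham array had 29 genes above and 21 below both others, and the untreated array 10 and 13. Higher genes made up 80% of the calls, against 60% with values as deposited, 65.8% with 75th percentile scaling and 67.6% after quantile normalization; the median of all genes on this array lay 0.13 above sham on the log2 scale. With the floor at the 60th percentile the number of lower genes was 0.

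The late pool, at 24 to 40 h, had 22 genes higher and 38 lower than both controls. Ccl2 (4.82-fold and 5.27-fold), Mmp12 (at least 4.76-fold above sham and 4.33-fold above untreated), Orm1 (4.33-fold and 6.43-fold), Nos2 (3.01-fold and 3.09-fold) and Ccl3 (2.69-fold and 2.52-fold) were still higher. The circadian transcription factor Dbp was at 2933 against 699 and 1051, and its second probe set read 864 against 216 on the untreated array and a value under the floor on the sham array. Osteopontin, Spp1, a secreted phosphoprotein of macrophages and matrix, was 2.72-fold and 3.88-fold higher, the inhibitory Fc receptor Fcgr2b 3.87-fold and 2.51-fold, and the cathepsin Ctsk 3.28-fold and 2.13-fold. Top2a, a topoisomerase of dividing cells, was 2.43-fold and 2.32-fold higher, and the mitotic gene Wdr62 at least 2.47-fold above both. Uck2 and Hoga1 were at least 2.95-fold and 3.16-fold above sham.

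Cell cycle genes had their highest median on this array, 0.38 (percentile 99.98), with Top2a and Mcm6 past 2-fold and 17 of 19 not. Other probe sets above the floor did not pass: they gave 0.58 for Top2a and 0.63 and 0.52 for Mcm6 (log2 difference from the mean of the controls). Macrophage and monocyte markers had a median of 0.41 (percentile 99.8), with Fcgr2b and Ctsk higher among 10 measured. Cytokines and chemokines had 4 of 21 members higher (Ccl2, Spp1, Ccl3 and Cxcl10; median 0.38, percentile 100) and acute phase and innate effectors 2 of 25 (Orm1 and Nos2; median 0.20). No immediate early gene (median 0.09) and no heat shock gene (median 0.32) passed. In the antioxidant list Gpx2 alone was lower. The median of that list, 0.03, lay under the 0.16 of matched random lists (percentile 0.9). In the matrix list Mmp12 and Spp1 were higher (median 0.11), and in the coagulation list Nos2 (median 0, mean 0.09).

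The 38 lower genes of the late array included Tmem69 (195 against 928 and 849, log2 differences of -2.25 and -2.12), Vcf1 (-1.97 and -1.86), the phosphatases Ptpn3 (-1.78 and -1.80) and Ppm1b (-1.55 and -1.69), the Mediator subunit Med6 (-1.74 and -2.08), and the DNA repair gene Xrcc5 (-1.75 and -1.61). The sarcomere protein Actn2 and the brown fat uncoupling protein Ucp1 were at the floor on this array, Actn2 at least 3.73-fold and 5.26-fold and Ucp1 at least 3.28-fold and 3.11-fold below sham and untreated. Probe sets of the rc_AA series, made from ESTs, read 76.3% of these 38 genes and 34.1% of the genes that could have passed. Of the 38, 12 had another probe set above the floor on some array; for 5 of them both controls were bright enough for a lower call, and none passed. Without EST probe sets, a setting chosen after seeing the data, 10 genes were lower and 15 higher, against 13 and 16 for the sham array in the same trio. Over all probe sets, the sham array had 19 genes above and 21 below both others, and the untreated array 18 and 14. Higher genes were 36.7% of the late calls, against 25% with values as deposited.

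**Figure D2:**
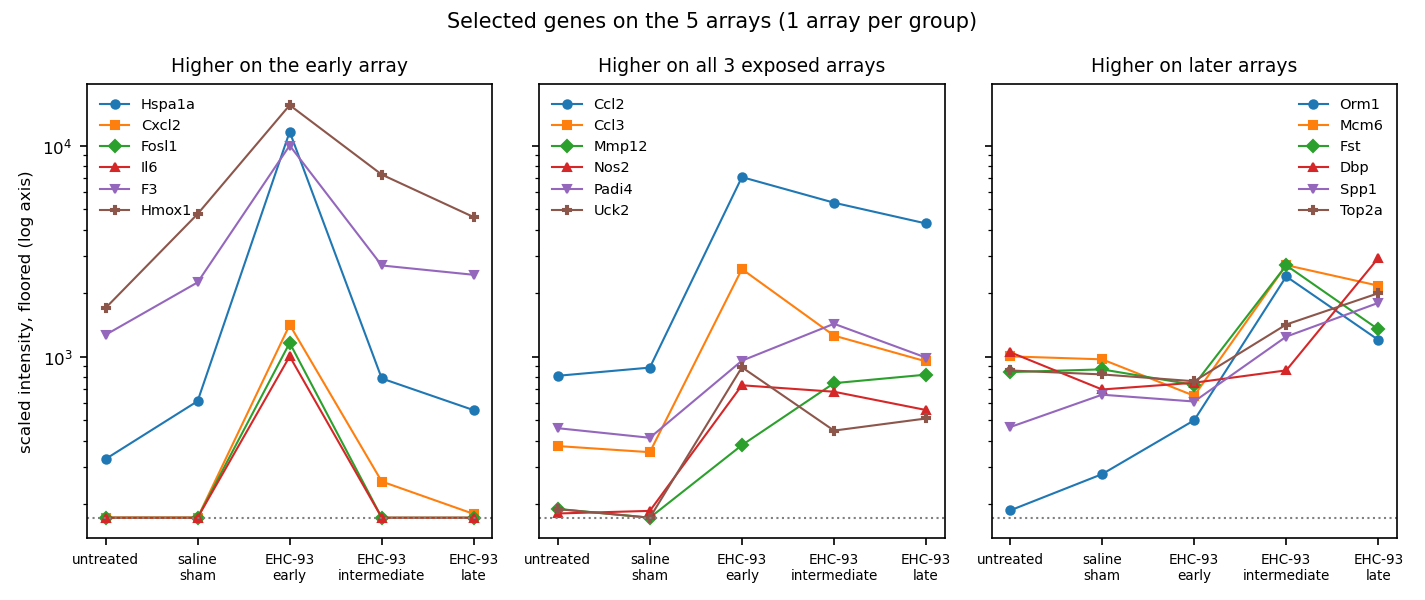
Scaled intensity, floored at 172.5 (dotted line, log axis), of 18 genes on the untreated, sham, early, intermediate and late arrays, 1 array each, lines joining the points of a gene. Hspa1a, Fosl1 and Il6 peaked on the early array, Ccl2 stayed between 7097 and 4277 on the exposed arrays against 888 and 812, and Dbp was highest on the late array.

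Across the 3 exposed arrays, 6 genes were higher than both controls on each by their main probe sets: Ccl2, Ccl3, Mmp12, Nos2, Padi4 and Uck2. Independent lists of these sizes among 3667 genes would share 0.00487 genes. In 100 simulations of unchanged arrays against the same controls none was shared, with 1.51 higher calls per array. These arrays were drawn around the mean of the 2 observed controls, so they seldom pass both. They cannot show overlap that comes from error in the controls and are no yardstick for it. Part of the excess may come from the shared control arrays, which cannot be split. No gene was lower on all 3. Early and intermediate arrays shared 12 higher genes, intermediate and late arrays 10, and early and late arrays 6. In the same simulations the shared higher genes numbered at most 1, 1 and 0, and independent lists of these sizes would share 0.812, 0.192 and 0.558; neither value allows for both the shared controls and real effects.

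The phases were also compared directly, without the control arrays. The early array had 65 genes at least 2-fold above and 26 below both later arrays, the intermediate array 16 and 5, and the late array 4 and 45. Hspa1a (14.8-fold over intermediate and 20.9-fold over late), Fosl1, Il6, Cxcl2 and Cav1 (8.39-fold and 4.97-fold) led the early array, and the transcription factor Casz1, the pentraxin Nptx2 and Mcm6 were lowest there, Mcm6 at 653 against 2716 and 2170. Ggt1, the channel Trpc1, the kinase Stk38, Tgfb3 and Ndrg4 were highest on the intermediate array, Stk38 at 5988 against 2086 and 1840, while Serpind1, Apob and the cyclic AMP regulator Crem were lowest. Other probe sets did not bear out all of these orders: one of Tgfb3 read 570 on the early, 489 on the intermediate and 406 on the late array, one of Ndrg4 351, 542 and 562, and one of Crem 256, 177 and a value under the floor. A second Nptx2 probe set read 175 and 174 on the early and intermediate arrays and lay under the floor on the late array, and a second Trpc1 probe set lay under the floor on all 3. Dbp (3.90-fold over early and 3.41-fold over intermediate), the carboxypeptidase Cpz, the embryonic globin Hbe2 and the kinase Fgr were the 4 genes highest on the late array. Triobp, Tmem69 and the phosphodiesterase Pde4b (1131 against 5558 and 4114) were lowest on it, and without EST probe sets 3 genes rather than 45 were lowest on the late array. One other Pde4b probe set read 297 on the late array against 482 on the early and 214 on the intermediate array. Another lay under the floor on the late array against 444 and 185.

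Saline instillation itself was set against no instillation. The sham array had 57 genes at least 2-fold above and 59 below the untreated array. Lipocalin Lcn2, a neutrophil and epithelial protein of innate defence, was at 20334 against 5976 and reached 30982, 49008 and 38177 on the early, intermediate and late arrays. The chemokine Xcl1 (at least 4.51-fold), C2cd4b (at least 4.05-fold), the poliovirus receptor Pvr, the proteoglycan Spock2 and the transcription factor Gata4 were the other leading genes on the sham array. Casz1, Arhgap39 and the dynamin Dnm1 were at the floor on the sham array and at least 4.24-fold, 3.83-fold and 3.57-fold below the untreated array, and the creatine synthesis enzyme Gamt, Cnksr3 and Ppdpf had log2 differences of -1.68, -1.59 and -1.51. A second Gamt probe set went the other way, at 545 on the sham and 206 on the untreated array, and second probe sets of Gata4 and Ppdpf lay under the floor on both. In the acute phase list 3 of 25 genes were higher on the sham array (Lcn2, Socs3 and Cebpd; median 0.18, percentile 100), whereas in the cytokine list Ccl5 was lower and none was higher (median 0). The central 95% of log2 sham minus untreated differences ran from -1.19 to 1.05 in the second of 4 signal classes and from -0.60 to 0.42 in the brightest. Higher genes were 49.1% of these calls, against 64.9% with 75th percentile scaling.

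By their main probe sets, surfactant genes Sftpc, Sftpa1 and Sftpb stayed within a log2 difference of 0.56 of both controls on every exposed array. A second Sftpa1 probe set lay 0.61, 0.37 and 0.60 above the mean of the controls on the early, intermediate and late arrays. Medians of the alveolar type 2 list (5 genes) were -0.06, 0.43 and 0.41 in the same order, with none passing. Matched random lists had medians of -0.04, 0.27 and 0.24, which put the list at percentiles 43.8, 90.8 and 95.2. Club and airway secretory markers had medians of -0.33 (percentile 0.965), -0.10 (percentile 1.11) and 0.04 (mean -0.07), with none of 7 passing. For sham against untreated their median was -0.27 (percentile 1.19), and Cyp2f4 was the 1 member to pass, as lower. Alveolar type 1 markers gave 0.27, -0.04 and -0.01, with Cav1 passing upward early and downward at the intermediate times. Random lists matched to them had medians of -0.04, 0.22 and 0.20 (percentiles 92, 4.8 and 6.7). Neutrophil markers S100a8 (2.60-fold and 3.94-fold) and S100a9 (2.13-fold and 2.91-fold) were higher on the early array and S100a9 on the intermediate array, but 4 of 7 markers were at the floor on every array, so list medians were 0. Cd14 was the 1 macrophage marker of 10 higher on the early array (median 0, mean 0.31), and none passed on the intermediate array (median 0.34).

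T and B lymphocyte markers (14 genes) had medians of -0.01, -0.16 and 0, and -0.31 for sham against untreated. Endothelial markers (7 genes) gave -0.01, -0.03 and 0.22, with means of 0.08, 0.06 and -0.01. Ciliated (4 genes) and mast cell (11 genes) markers had medians of 0 on the early and intermediate arrays and of 0.16 and 0 on the late array. Interferon response and antigen presentation genes (16) gave -0.15, 0.12 and 0.20, with none passing, and -0.22 for sham against untreated. Matched random lists had medians of -0.001, 0.21 and 0.16, and -0.08 for sham. The percentiles were 5.68, 15.2 and 72.9, and 2.56 for sham, so the intermediate value lay under that of random lists. Of 4 red cell transcripts none passed on an exposed array, and Hbb alone passed for sham against untreated. Hbb was at 10501 on the early and 9118 on the sham array against 4017, 5403 and 3544 on the intermediate, late and untreated arrays, Alas2 lay between 513 and 726 on the 5 arrays, and the list had medians of 0.48, -0.27 and 0.13, and 0.56 for sham against untreated. The intermediate value was 0.12 against the untreated array alone.

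Cardiac muscle markers were lower on each instilled array than on the untreated one, and these moved beside the lower genes of the early and late arrays. Troponin Tnni3 was at 2762, 5891, 2164 and 4800 on the early, intermediate, late and sham arrays against 9340 on the untreated array, and atrial myosin light chain Myl7 at 6826, 12018, 4937 and 10462 against 17266; both passed as lower on the late array. Medians of the 17 cardiac markers were -0.80, -0.14 and -1.20 from the mean of both controls, and the intermediate value was 0.20 against the sham array alone. Adipocyte markers (6 genes) had medians of -0.46, -0.43 and -0.69, with Cfd lower on the early and late arrays and Ucp1 on the intermediate and late arrays; for sham against untreated the median was 0.04 and the mean -0.17. Smooth muscle markers (8 genes) gave 0.01 (mean -0.11), 0.25 and 0.06 (mean -0.04), and for sham against untreated all 8 were lower by some amount, with a median of -0.34. Their percentiles among matched random lists were 54.8, 75.5 and 25.7, and 1.19 for sham. Skeletal muscle markers (11 genes) gave -0.05, 0 and 0. The 5 reference genes had medians of 0.01, 0.32 and 0.26 (percentiles 60.8, 75.7 and 65.4) and none passed. Pgk1 reached 0.97 and 0.85 above sham and untreated on the intermediate array. Of the 78 list medians on exposed arrays, 11 had another sign under another scaling, among them the alveolar type 2 and reference lists on the early array, the interferon list on the intermediate array, the club and smooth muscle lists on the late array and the antioxidant, matrix, coagulation and immediate early lists on the intermediate array. None of these 11 was larger than 0.18, and the median of all genes on the early array was itself -0.11 with 75th percentile scaling.

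**Figure D3:**
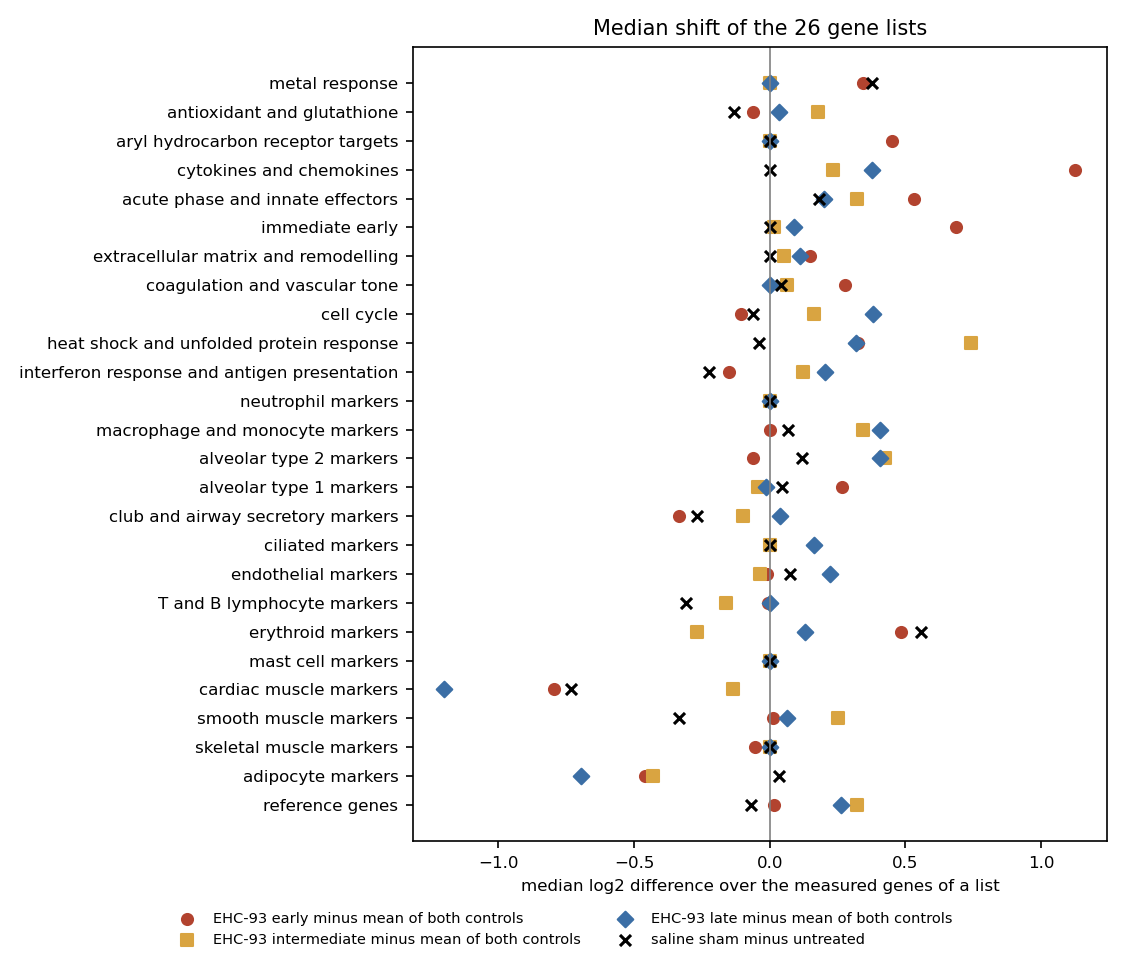
Median log2 difference (horizontal axis) over the measured genes of each of 26 gene lists, for the early (circles), intermediate (squares) and late (diamonds) arrays minus the mean of both controls and for sham minus untreated (crosses). Cytokines and chemokines lay at 1.13 on the early array, and cardiac muscle markers at -1.20 on the late and -0.73 on the sham array.

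To ask what the 3 exposed arrays shared against the 2 arrays without particles, a linear model was fitted with limma. Ccl2, 2.69 higher on the log2 scale (SE 0.24), and Nos2, 1.83 higher (SE 0.17), had the smallest p-values, each with a Benjamini-Hochberg adjusted p = 0.147. By their main probe sets both were above both controls on 3 of 3 exposed arrays. Nos2 read 186 on the sham and 181 on the untreated array, near the floor of 172.53. Its 2 other probe sets above the floor on some array did not match it on the early and late arrays, and 1 of them not on the intermediate array. Gfy, Lmbr1l, Slc8a2 and Abcb4 (lower) and the granulocyte enzyme Padi4, the lysosomal membrane protein Lamp2, Ctrc and Prm2 (higher) followed with an adjusted p of 0.610. No gene of 3667 passed the threshold of 0.05, while 176 genes were higher and 80 lower at an unadjusted p under 0.05. That split depended on the scaling. It was 87 and 163 with values as deposited, 107 and 134 with 75th percentile scaling, and 112 and 116 after quantile normalization. With trend and robust empirical Bayes 1 gene passed, Ccl2 (adjusted p = 0.0352), and without a filter on low values 1 gene, Prm2 (adjusted p = 0.0445), which lay near the floor. Adjusted over the list alone, 4 cytokines and chemokines, 3 adipocyte markers, 2 macrophage markers, 1 acute phase gene, 1 neutrophil marker and 1 coagulation gene passed, against 0 over all genes.

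As sets, 5 lists were higher on the exposed arrays by limma's camera with a preset correlation: acute phase and innate effectors (median 0.60, adjusted p = 2.82e-05), cytokines and chemokines (median 0.68, adjusted p = 3.33e-05), heat shock and unfolded protein response (median 0.51, adjusted p = 0.000321), macrophage and monocyte markers (median 0.45, adjusted p = 0.0116) and neutrophil markers (median 0.97, adjusted p = 0.0120, 3 genes). With an estimated correlation each of these 5 had an adjusted p = 0.502. Cardiac muscle markers (median -0.76, adjusted p = 1.57e-05), adipocyte markers (median -1.13, adjusted p = 0.00101) and T and B lymphocyte markers (median -0.10, adjusted p = 0.0472) were lower. With an estimated correlation their adjusted p was 0.557, 0.502 and 0.557. Without the untreated array none of the 8 calls was left, and the adjusted p by camera ranged from 0.104 for adipocyte markers to 0.574 for T and B lymphocyte markers, whose median was then 0.06. The neutrophil call was also lost without the early or the intermediate array, with the floor at the 20th or 60th percentile and without a filter on low values, and the T and B lymphocyte call without the intermediate array, with the floor at the 20th percentile, after quantile normalization, with the mean of all probe sets and without suffixed probe sets. The median or mean had another sign than the camera direction for the alveolar type 1 (median 0.03), mast cell (median 0.05) and endothelial (mean 0.04) lists, each with the direction down and an adjusted p of 0.906.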

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

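The tests of RNA integrity, of the EST probe sets and of cardiac tissue were chosen after the results were seen; their bootstrap intervals resample genes and cover no error between arrays.

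Probe sets without a single gene name held signal that the gene counts leave out. Of 1734 such probe sets, 31 were at least 2-fold higher on the early array than on both controls, 8 on the intermediate and 6 on the late array. The highest, annotated to several genes, had an intensity of 4499 on the early array and lay under the floor on the other 4, at least 26.1-fold higher; another read 21668 against 1418 on the sham and 423 on the untreated array. Cav1 differed in direction between phases, at 1.74 above the mean of the controls on the early and -1.33 on the intermediate array (log2), a difference that was not tested since each phase has 1 array.

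The early array stood out in the control transcripts, which the gene comparisons do not use: its 5′ to 3′ ratio was 43.1% for beta-actin and 67.2% for GAPDH, above both control arrays. If a lower loss of 5′ ends were the whole reason for the 93 higher genes, the untreated array, with higher ratios than sham, should read them higher too, but the median log2 difference untreated minus sham was -0.0497 (95% bootstrap interval -0.18 to 0), with 51 genes higher on sham and 30 higher on untreated. Since the interval reaches 0, a second test was added after this one had left the matter open: intermediate minus late, whose ratios also differ, had a median of 0 (-0.04 to 0.07), which decides nothing either. Within genes that have both kinds of probe set, the cDNA probe set exceeded the EST probe set by a median of 0.28 on the early array in 13 of the higher genes (-0.72 to 0.98), too wide to tell; over all 335 such genes the excess was 0.06 (0.02 to 0.13) on the early and -0.07 (-0.12 to -0.03) on the intermediate array. An early response to the particles and a less degraded early pool therefore cannot be told apart by these tests as causes of the higher calls. Each may contribute. The sham pool held 2, 15 and 24 h and the early pool 2, 4 and 6 h. A response to instillation itself in the first hours was therefore not matched by the sham array and cannot be told apart either.

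The 38 lower genes of the late array may reflect probe sets rather than genes. Probe sets of the rc_AA series read 76.3% of them, against 34.1% of the 2369 genes that could have passed, 63.2% at most in 10000 random draws, 23.8% of the lower genes of the sham array and 42.9% of those of the untreated array. Of 12 genes with at least 1 other probe set above the floor on some array, 8 had at least 1 that lay below both controls. Other probe sets of a gene could differ: those of Ppm1b gave -0.41, 0.16 and 0 (log2 difference from the mean of the controls). In 5 genes at least 1 was bright enough on both controls for a lower call, and none passed. What sets this series apart on the late array is open, and a biological fall of part of these genes was not excluded.

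Cardiac muscle markers were lower on the instilled arrays than on the untreated one. A lower share of heart muscle in the pooled lung tissue may account for this on the exposed arrays, where cardiac medians were -1.20, -0.52 and -1.60 on the early, intermediate and late arrays against -0.27, 0.10 and -0.10 for smooth muscle markers, differences of -0.93 (95% bootstrap interval -1.35 to -0.41), -0.62 (-1.01 to -0.34) and -1.49 (-1.84 to -0.84). On the sham array it stays open, since smooth muscle markers were lower there too, at -0.34 (-0.59 to -0.01) against -0.78 for cardiac ones, a difference of -0.44 (-0.76 to -0.06). Loss of 5′ ends is argued against by the early array, which had the highest ratios and yet a cardiac median of -1.20 (-1.37 to -0.47) against untreated. Rat pulmonary veins carry a sheath of heart muscle, so a change in that tissue stays open, and the effect of exposure itself was not tested.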

How the results depend on the processing

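EST settings and the sterol alternatives were chosen after seeing the data. List medians over only the genes above the floor were not planned beforehand either. All other alternatives were fixed before. Of 809 values of named genes under alternatives, 705 moved by less than the sham to untreated spread, 103 moved by more and 1 turned; of 777 list medians per phase, 614 moved by less than the spread of random lists, 161 by more and 2 turned; of 334 camera results, 297 kept their side of the threshold, 25 lost a call and 12 gained one. No paired analysis was possible because each group has 1 array. At most 68.6% of the genes lay above the floor on an array, which limits what can be seen. Where no cause is named, the cause was not tested.

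Counts are given as higher and lower genes for early, intermediate and late exposure against both controls (93 and 11, 32 and 8, 22 and 38), for sham against untreated (57 and 59), and for the early, intermediate and late array against the other phases (65 and 26, 16 and 5, 4 and 45). A 1.5-fold threshold, which by construction passes more genes, gave 251 and 109, 174 and 58, 112 and 127, then 236 and 275, then 198 and 203, 116 and 71, 50 and 127. A 3-fold threshold gave 23 and 0, 9 and 0, 4 and 7, then 8 and 5, then 18 and 4, 2 and 0, 1 and 9. With the floor at the 20th percentile they were 146 and 66, 103 and 60, 92 and 93, then 288 and 227, then 111 and 86, 86 and 67, 54 and 106, and 5 lists rather than 3 were higher on the intermediate array. With the floor at the 60th percentile, fewer genes can pass: 53 and 3 early, 0 lower intermediate, 12 and 21 late, 9 and 17 for sham, and 38 and 12, 8 and 0, 1 and 25 between phases.

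Against the sham array alone the counts were 158 and 68, 87 and 59, 74 and 84, and against the untreated array alone 148 and 75, 88 and 34, 64 and 98, since 1 reference is easier to pass than 2; 7 lists rather than 4 were then higher on the late array. With values as deposited, 18 genes were lower early, 21 higher and 14 lower at the intermediate times, and 10 were highest on the intermediate array. With 75th percentile scaling 21 were lower early and 13 lower at the intermediate times. With the mean of all probe sets 6 were lower early, 15 lowest on the early and 2 lowest on the intermediate array, and 3 lists rather than 5 were lower on the intermediate array. Without suffixed probe sets 5 were lower early, and 5 lists were higher on the intermediate array.

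EST probe sets alone, with fewer genes, gave 34 and 3, 11 and 3, 7 higher late, 18 and 31 for sham, and 18 and 12 for early, 7 higher for intermediate and 0 higher for late between phases. Without EST probe sets 10 genes were lower late, 31 lower for sham, 16 lowest on the early, 9 highest on the intermediate and 3 lowest on the late array. Turned in direction were the cardiac list on the intermediate array against sham alone (0.20), the erythroid list on the intermediate array against untreated alone (0.12) and Pde4b on the late array without EST probe sets (0.22).

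In limma, trend and robust eBayes and no filter each gave 1 higher gene instead of 0; leaving out each array in turn gave 0 to 0 higher and 0 to 0 lower genes, the lone sham or untreated array then being assumed to vary like the others. Camera called 5 lists higher and 3 lower; leaving out each array in turn gave 0 to 7 higher and 0 to 4 lower lists, newly called lists included. Of the 8 calls, 7 were kept without the early, 6 without the intermediate, 8 without the late, 8 without the sham and 0 without the untreated array. An estimated correlation left 0 higher and 0 lower.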

Other observations

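The sterol and amino acid tests were written after some members had been seen but before the values of the members tested here.

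In cholesterol synthesis, Idi1, the isopentenyl diphosphate isomerase, was at 1877 on the early array against 658 on sham and 550 on untreated, and Fdft1, squalene synthase, was at 1314 on the late array against 634 and 528; both were picked because they were high. Of 12 other members, none passed the 2-fold rule on an exposed array, and 9, 12 and 11 lay above the mean of the controls by any amount on the early, intermediate and late arrays, with 3 below it on the early array. Among these 12 members of the pathway, the squalene epoxidase Sqle was at 1515, 1353 and 1694 on the early, intermediate and late arrays against 997 and 1162, the methylsterol oxidase Msmo1 at 3791, 3682 and 3990 against 2402 and 2420, and the farnesyl diphosphate synthase Fdps at 2157, 1661 and 2233 against 1288 and 1363. Acat2 was lower on sham than on untreated.

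On the early array, 5 genes of amino acid transport and metabolism or of stress were picked because they were high. Asparagine synthetase Asns was at 532 against 235 and 151, the pseudokinase Trib3 at 841 against 357 and 285, the cationic transporter Slc7a1 at 881 against 335 and 231, the neutral transporter Slc7a5 at 1945 against 820 and 775, and the aminotransferase Bcat1 at 500.2 against values under the floor. Among clock genes, Dbp was 1.78 above the controls on the late array, Bhlhe41 was at 0.39, Tef at 0.30, Nr1d2 at 0.20 and Nr1d1 at -0.12. Bhlhe40 and Per2 read 249 and 213 there against controls under the floor, and Bmal1 and Hlf lay under the floor there against 222 and 270 for Bmal1 and 196 and 189 for Hlf. The times of day of the pools are not given in the sources used here.

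A hypothesis of raised sterol synthesis predicted that the 12 members not seen before would stand above the central 95% of matched random lists on the early array. Their median was 0.36 on the log2 scale (bootstrap interval over these genes, added later, 0.03 to 0.64), at percentile 99.2. That interval also reaches below the bound of 0.26 set by random lists. On the intermediate and late arrays the median was 0.40 and 0.69 (percentiles 99.1 and 100). Across the other scalings, floors, probe set choices and references the early percentile ran from 96.4 without suffixed probe sets to 99.8 with the mean of all probe sets, and the median stayed above 0. The value of 96.4 lies within the central 95%, so the prediction failed with that setting; the cause was not tested. With the other settings the values are consistent with a small shift of the pathway and say nothing of its source. For sham against untreated the same members had a median of 0.04.

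A hypothesis of an amino acid response on the early array, drawn from Asns, Trib3, Slc7a1, Slc7a5 and Bcat1, was tested on 7 further members. Their median was 0.12, at percentile 86.7 of matched random lists, short of the central 95% that the prediction asked them to pass. They went both ways: Slc3a2, Nupr1, Eif4ebp1 and Psat1 were at 0.47, 0.45, 0.28 and 0.12, Cth was under the floor on every array, Phgdh was at -0.14, and Vldlr lay under the floor against 254 on sham and 174 on untreated. The prediction, as written before, therefore failed. The bootstrap interval of the median over these genes, added after the percentile was seen, ran from -0.14 to 0.45. It reaches past the bound of 0.26 set by random lists, so these 7 genes do not exclude a shift of the list either.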
